A study of Mus musculus with 16 samples.

How the data were processed

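RNA was measured on 16 Illumina mouse bead arrays, each hybridised with biotinylated cRNA made from total RNA of prostate tissue, per the labels' protocols. Of these arrays, 6 held neuroendocrine carcinomas (NECa) of TRAMP mice, 8 held dorsal-lateral prostate (DLP) and 2 held whole prostate of wild-type mice. The groups and replicate numbers were taken from the sample labels. The labels do not state whether the replicates of a group came from separate animals or whether RNA of several mice was pooled for a DLP array, so the p-values measure the spread between these samples.

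The deposited table held linear, normalized probe intensity values for 25697 probes, and lumi was the tool named in the submitters' processing notes, without a version. The normalization method and the treatment of background were not given in the sources used here. The values showed that the background had not been brought to 0: the lowest intensity of an array lay between 113 and 139, the median between 151 and 166, the upper quartile between 312 and 337, and the highest between 20502 and 69911. Differences of weakly expressed genes are therefore compressed on this scale, and a log2 difference is a lower estimate for a gene near 150. The number of arrays limits the precision. A deposited table of values before normalization was not used, because its 32 columns of per-sample values, 16 of them signals, carried names that matched no sample label. Detection p-values were therefore not available for filtering, and all probes were tested.

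Probe names came from the platform annotation. It listed 23978 probes with 1 symbol and 0 with several, and 1719 probes were not listed and stayed unnamed. Through the Entrez identifier, 23962 probes matched the RefSeq gene table of assembly GRCm38.p6, which was used only for names, chromosomes and gene order, and 0 symbols changed. The named probes covered 16593 genes, of which 4777 had more than 1 probe. A gene was represented by its probe with the highest mean level over all 16 arrays, and disagreeing probes are stated beside the gene. Mki67 had no matching probe in the table and was not analysed here.

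Intensities were brought to log2 and fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend. All limma and gene list tests were two-sided. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all 25697 probes. AGN and vehicle carcinomas were compared on the 6 carcinoma arrays alone. Each carcinoma group was compared with the wild-type prostates in a fit of 8 arrays that shared 1 spread. The DLP arrays had no replicates at a given age, so the 8 arrays were fitted with additive terms for 4 treatments and 2 ages. That fit has 3 residual degrees of freedom, and they hold array noise together with any dependence of a treatment effect on age. An interaction term over all 16 arrays tested whether the AGN effect differed between carcinomas and DLP. At a single age, differences of a pair of DLP arrays were counted at an absolute log2 difference of at least 1 and were not tested.

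For the gene lists, 36 lists of pathway members and cell type markers were written out before the data were examined, as were the comparisons, fits, thresholds, naming rule and the first set of alternative settings. They were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 36 lists of a comparison. The fry test asks whether the genes of a list move one way on balance and does not compare them with other genes. No list reached an adjusted p under 0.05 with an estimated correlation in any of the 9 comparisons, and this p is given beside the lists described. Counts of called list members are given over all probes and adjusted over the list alone.

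Per comparison, the naming rule took the 12 highest and 12 lowest log2 fold changes among genes with 1 symbol that were called, that were not unnamed clones, and whose groups did not overlap or, in DLP, had the same sign at both ages. It added the members with the 3 largest changes of each list described, and Pbsn, Chga, Syp and Ezh2 in every comparison. Where fewer than 10 genes passed, it took the genes with the 10 smallest p-values as not passing, and in DLP those with the largest differences of the same sign at both ages. The clone 6330403K07Rik lies outside this rule and was named after its values were seen, because it was among 10 called probes.

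Correlations of effects across probes were computed in DLP between differences that share no array, by taking one from 16 weeks and the other from 28 weeks. Same-age differences share the vehicle array, and their values are set beside 20 simulations of unchanged groups against shared arrays. The simulated spread of each probe was the residual SD of the additive fit of the 8 DLP arrays. Probes are not independent replicates, so these correlations carry no p. Chromosome medians used 8920 genes above the median level and were examined after the carcinoma comparison had been seen.

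The fits were tested on simulated data in 30 draws per comparison, with 25697 probes of which 200, all above the median level, were changed. The full change was added to the log2 values, without compression by background. The shares recovered below therefore do not hold for dimmer probes and can overstate the power for compressed ones. They also hold only with 200 changed probes, part of them changed 4-fold. With fewer true changes the adjusted threshold is stricter and smaller shares would be recovered, which was not simulated. A fit with 0 calls therefore does not exclude 2-fold changes of a few probes. With spreads drawn from the fitted prior, between 4.29% and 5.40% of the calls were false. With spreads taken as the residual SD of each probe this share was 3.05% to 4.70%, and with shrunken SDs it was 5.09% to 10.4%. With the fitted prior, 2-fold changes were recovered in 88.3% of cases for AGN against vehicle carcinomas, 92.5% for vehicle against wild-type DLP, 93.3% for AGN and 91.7% for D/DA against vehicle DLP, and 62.2% for the interaction. With residual SDs these shares were 77.1%, 76.9%, 76.5%, 77.1% and 64.8%.

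The alternatives were quantile normalization, median centring, only probes above the median level, no intensity trend, array weights, other sets of arrays in the fit, the replicate number as a block, a fold minimum and leaving out each array in turn. After the data had been examined, normexp background correction with an offset of 16, gene-by-gene array weights, the adipocyte or skeletal muscle list level as a covariate, leaving out chromosome 19 genes, and leaving out NECa vehicle 1 and NECa AGN 2 together were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.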

Results

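Gene expression was profiled in prostate tissue of TRAMP mice, in which the probasin promoter drives SV40 T antigen in prostate epithelium and lesions arise with age, and of wild-type mice. TRAMP mice had received vehicle, a root extract of Angelica gigas Nakai (AGN), or decursin and decursinol angelate (D/DA), pyranocoumarins of that root. The carcinoma part comprised 3 neuroendocrine carcinomas (NECa) of vehicle mice, 3 NECa of AGN mice and 2 whole prostates of wild-type mice aged 24 to 28 weeks. The strain field of these 2 control arrays names TRAMP although their label names wild type, and they were used here as wild type. The dorsal-lateral prostate (DLP) part comprised 1 array for each of wild type, vehicle, AGN and D/DA at 16 and at 28 weeks, so differences at a single age have no replicates. Replicate arrays of a group correlated with r between 0.969 and 0.987 across probes and shared 0 identical values. The first principal component held 76.6% of the variance and the second 9.07%. The doses of AGN and D/DA were not given in the sources used here.

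The first comparison asked how NECa differ from the normal gland. In the 3 vehicle NECa, genes of cell division and of the neuroendocrine lineage rose against the 2 wild-type prostates. The mitotic kinase gene Pbk rose by 5.06 ± 0.21 on the log2 scale (limma adjusted p = 2.52e-08) and the centromeric histone gene Cenpa by 4.95 ± 0.13 (limma adjusted p = 1.31e-09), where ± is the standard error of the fit. Insm1, a zinc-finger transcription factor of neuroendocrine cells, rose by 4.80 ± 0.17, from an intensity of 146 ± 11.1 (SD, n = 2) to 4049 ± 364 (SD, n = 3). Ddc, which makes dopamine and serotonin from their precursors, rose by 4.71 ± 0.26, the growth factor gene Mdk by 4.59 ± 0.22, Chga, which encodes the granule protein chromogranin A, by 3.11 ± 0.19 and the synaptic vesicle gene Syp by 2.43 ± 0.21. Of the fixed lists, 36 of 40 measured proliferation genes rose (36 adjusted over the list alone; camera adjusted p = 0.117 with an estimated correlation). Of 38 neuroendocrine markers 26 rose (28 adjusted over the list alone; camera adjusted p = 0.117 with an estimated correlation). Of 13 polycomb and DNA methylation factors 7 rose, or 7 with 1 that fell when adjusted over the list alone (camera adjusted p = 0.365 with an estimated correlation). They included the histone methyltransferase gene Ezh2 at 2.82 ± 0.16, called by 2 of its 3 probes, and the maintenance DNA methyltransferase gene Dnmt1 at 2.53.

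Genes of prostate secretion and of luminal epithelium fell in vehicle NECa. Tgm4, the prostate transglutaminase, fell by 8.80 ± 0.14 on the log2 scale (limma adjusted p = 2.69e-11), from an intensity of 67678 to 152. The microseminoprotein gene Msmb fell by 7.93 ± 0.80, the protease inhibitor gene Spink1 by 8.35 ± 0.40 and probasin, Pbsn, by 4.20 ± 0.16. Of 19 secretory genes 17 fell (17 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.117 with an estimated correlation). Of 18 luminal markers 13 fell (13 adjusted over the list alone; camera adjusted p = 0.117 with an estimated correlation), among them the keratins Krt8 at -4.66 ± 0.55 and Krt18 at -4.40 ± 0.37. Of 20 unfolded protein response genes 15 fell (16 adjusted over the list alone; camera adjusted p = 0.377 with an estimated correlation), with the co-chaperone gene Dnajc3 at -3.38. Of 22 NRF2 and glutathione genes 13 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 0.297 with an estimated correlation), with the glutathione transferase gene Gstm2 at -5.90.

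Markers of tissues around the gland moved with these genes. Of 18 smooth muscle markers 16 fell (18 adjusted over the list alone; camera adjusted p = 0.297 with an estimated correlation), of 18 skeletal muscle markers 13 fell (16 adjusted over the list alone; camera adjusted p = 0.557 with an estimated correlation), of 9 seminal vesicle genes 7 fell (9 adjusted over the list alone; camera adjusted p = 0.297 with an estimated correlation) and of 15 adipocyte markers 11 fell (12 adjusted over the list alone; camera adjusted p = 0.341 with an estimated correlation). The mean log2 level of the skeletal muscle list was 11.10 in wild-type prostate 1 and 8.65 in wild-type prostate 2.

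In total, limma called 7378 of 25697 probes, 3181 higher and 4197 lower, for 5528 genes, and 9225 probes had an unadjusted p under 0.05. Of 36 lists, camera called 20 at the preset correlation and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and fry called 23. After normexp background correction 11844 probes were called, 3091 higher and 8753 lower, while the median over all probes moved to -0.36 on the log2 scale, and a minimum of 2-fold left 3052, 1228 higher and 1824 lower.

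The AGN NECa were set against the same 2 wild-type prostates. The 3 AGN NECa showed increases of Insm1 by 5.09 ± 0.17, Mdk by 5.14 ± 0.22, Chga by 3.33 and Ezh2 by 3.17. The imprinted gene Nnat, which encodes neuronatin, rose by 4.62 ± 0.28. Tgm4 fell by 8.84, the ribonuclease gene Rnase1 (-6.24 ± 0.18) fell, and so did Pbsn (-4.16). Of 40 proliferation genes 36 rose (36 adjusted over the list alone; camera adjusted p = 0.163 with an estimated correlation), and of 38 neuroendocrine markers 22 rose (27 adjusted over the list alone; camera adjusted p = 0.163 with an estimated correlation). Of 19 secretory genes 17 fell (17 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.149 with an estimated correlation). Limma called 7958 probes, 3713 higher and 4245 lower. Camera called 19 lists at the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05, and fry called 24. After normexp correction 12712 probes were called, 3220 higher and 9492 lower, with a median of -0.39 over all probes, and a minimum of 2-fold left 3231, 1281 higher and 1950 lower. This comparison shares its control arrays with the previous one, so likeness between the 2 is partly built in.

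The next comparison asked which genes differ between NECa of AGN and of vehicle mice, and it found few. The homeobox gene Dbx1, a regulator of interneuron identity in the neural tube, rose by 3.73 ± 0.32 (limma adjusted p = 0.00201), with an intensity of 3115 ± 1231 in AGN NECa and 236 ± 101 in vehicle NECa (SD, n = 3 each) and 148 ± 6.49 in wild-type prostate. Sct, which encodes the hormone secretin, rose by 1.27 ± 0.17 (limma adjusted p = 0.0408). Genes that fell were Fam171b at -1.88 ± 0.15 (limma adjusted p = 0.00201), the phosphatase gene Dusp26 at -1.97 ± 0.20 (limma adjusted p = 0.0073), the glutathione transferase gene Gstp2 at -1.26 ± 0.14 (limma adjusted p = 0.00868) and the whey acidic protein family gene Wfdc12 at -1.12 ± 0.12. Tac1, the precursor gene of substance P, at -1.03 ± 0.12, the ubiquitin ligase gene Neurl1a at -2.34 ± 0.32 (limma adjusted p = 0.0484), the complex I subunit gene Ndufv1 at -0.85 ± 0.12 (limma adjusted p = 0.0484) and the clone 6330403K07Rik at -3.13 fell as well. The 9 genes other than the clone lay on the same side of all vehicle NECa in 3 of 3 AGN NECa, as the naming rule required. The markers Chga at 0.22 ± 0.18, Syp at -0.25 ± 0.19, Ezh2 at 0.35 ± 0.15 and Pbsn at 0.05 ± 0.05 did not pass (limma adjusted p = 0.885, 0.885, 0.776 and 0.885). Of 38 neuroendocrine markers 0 passed over all probes and 2 fell when adjusted over the list alone (camera adjusted p = 0.733 with an estimated correlation), and of 40 proliferation genes 0 passed over all probes and 1 fell when adjusted over the list alone (camera adjusted p = 0.985 with an estimated correlation).

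**Figure D1:**
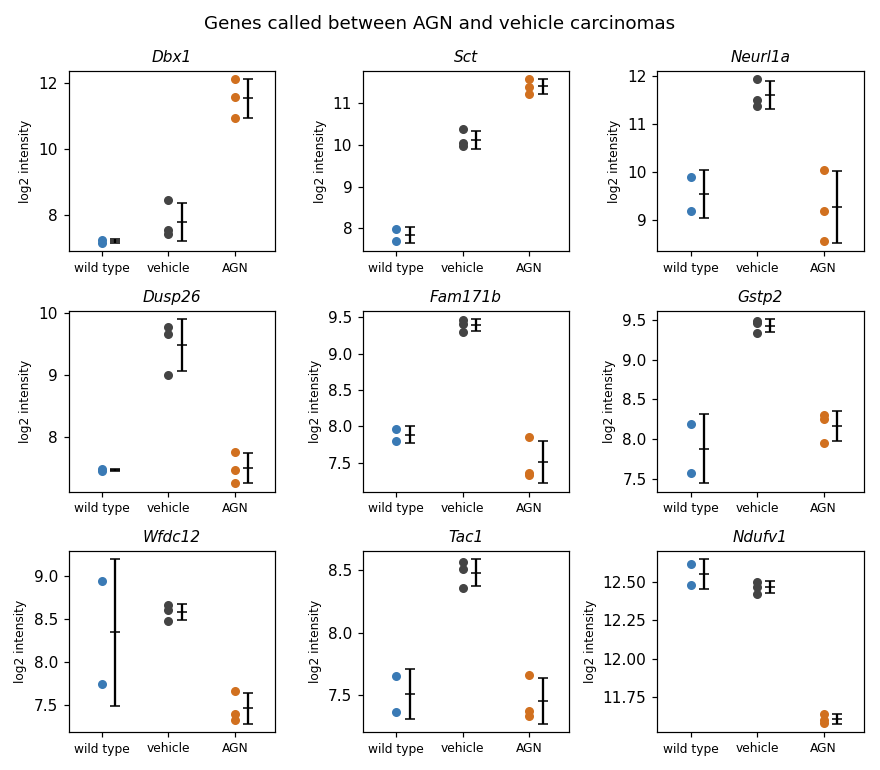
Log2 intensity of the 9 named genes called between AGN and vehicle carcinomas, with each point an array of wild-type prostate (n = 2), vehicle NECa (n = 3) or AGN NECa (n = 3) and the bar beside them the mean with its SD. Dbx1 and Sct lay higher in AGN NECa, by 3.73 and 1.27, and the other 7 genes lay lower; the vertical axes differ between genes and do not start at 0.

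Limma called 10 probes between AGN and vehicle NECa, 2 higher and 8 lower, and 1578 probes (6.14%) had an unadjusted p under 0.05. Camera called 8 lists at the preset correlation, all lower, and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05, and fry called 0, with 1 at an unadjusted p under 0.05. Single arrays set the number of calls: limma called 26 probes without vehicle 1, 45 without vehicle 3 and 72 without AGN 1. The calls of Dbx1, Dusp26, Fam171b, Gstp2, Wfdc12 and 6330403K07Rik held when any 1 array was left out. Sct missed the threshold without vehicle 2 (limma adjusted p = 0.146) or AGN 2 (0.125), and Tac1 without vehicle 2 (0.0569), AGN 2 (0.0802) or AGN 3 (0.0512). Neurl1a missed it without vehicle 1 (0.0668), vehicle 2 (0.143), AGN 2 (0.0502) or AGN 3 (0.0778). Ndufv1 missed it without vehicle 1 (0.0666), vehicle 2 (0.167), vehicle 3 (0.0695), AGN 2 (0.132) or AGN 3 (0.0778). Vehicle 1 and AGN 2 stood apart, vehicle 1 with a mean log2 level of 9.78 for fibroblast genes and 9.67 for macrophage markers, against 8.19 to 8.77 and 8.39 to 8.92 in the other NECa, and AGN 2 with 8.18 for secretory genes, against 7.35 to 7.65. Without these 2 arrays limma called 0 probes, with 1602 at an unadjusted p under 0.05. Limma also called 0 probes after normexp correction (2049 unadjusted) and 0 among probes above the median level (1335 unadjusted), 6 after quantile normalization or median centring, 35 without an intensity trend and 405 with gene-by-gene array weights.

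Of the 10 called probes, 3 lay on chromosome 19, those of Gstp2, Neurl1a and Ndufv1. Over 312 chromosome 19 genes above the median level, the median difference of AGN from vehicle NECa was -0.42 on the log2 scale, against 0.01 over all 8920 such genes and -0.03 to 0.09 on the other chromosomes. Of these genes 95.8% were lower in AGN NECa, and without overlap between the groups 204 of the 312 were lower and 1 was higher, where chance gives 10% for both directions together. Deviations were taken per gene from the median of the 6 NECa, as a median over the chromosome less that over all genes. For chromosome 19 they were -0.17 ± 0.015 in AGN and 0.20 ± 0.029 in vehicle NECa (SD, n = 3 each). The two-sided exact permutation p of 0.1 was the smallest that 3 against 3 allows. The chromosomes were compared after the data had been examined.

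**Figure D2:**
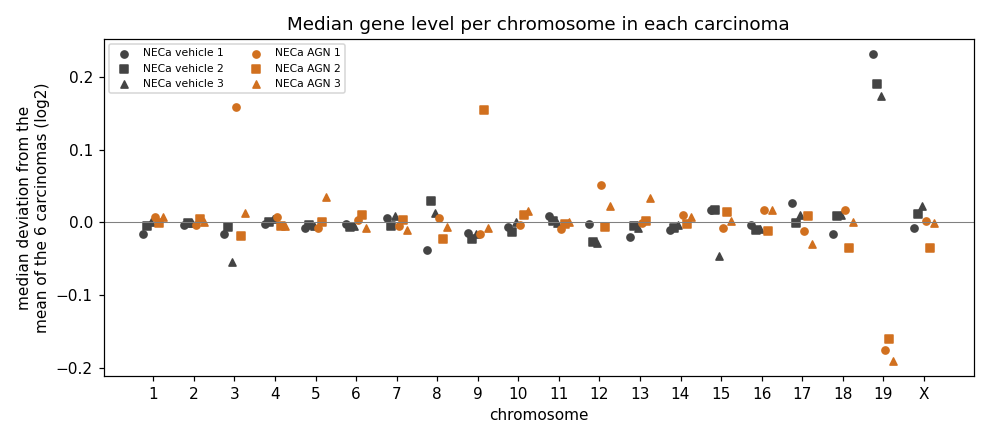
Median over genes of the log2 deviation from the median of the 6 carcinomas, less the median over all genes, for each chromosome (horizontal axis) and each NECa (points, grey for vehicle, orange for AGN). The vertical axis label names the mean, but the median of the 6 was used. On chromosome 19 the 3 AGN NECa lay below 0, on average at -0.17, and the 3 vehicle NECa above it, at 0.20.

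The comparison of vehicle-treated TRAMP with wild-type DLP asked how the gland of TRAMP mice differs before or apart from a dissected carcinoma, with no lesion stage given for these arrays. In the fit over both ages, the replicative helicase genes Mcm5 and Mcm6 rose by 3.02 ± 0.15 (limma adjusted p = 5.97e-05) and 2.75 ± 0.15, and the replication licensing gene Cdt1 by 2.64. The transthyretin gene Ttr rose by 3.75 ± 0.21, with 3.30 at 16 and 4.19 at 28 weeks, the lipocalin gene Obp2a by 2.79 ± 0.12 and the trefoil peptide gene Tff3 by 3.01 ± 0.44. Of 40 proliferation genes 32 rose (33 adjusted over the list alone; camera adjusted p = 0.363 with an estimated correlation). Of 13 polycomb and DNA methylation factors 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.363 with an estimated correlation), with Dnmt1 at 1.33 and Ezh2 at 0.85 ± 0.16 (limma adjusted p = 0.0165), called by 1 of its 3 probes while 1 had the opposite sign. Chga at 0.03 ± 0.05 and Syp at -0.18 ± 0.11 did not pass (limma adjusted p = 0.737 and 0.314). Of 34 interferon response genes 14 rose and 1 fell (21 and 2 adjusted over the list alone; camera adjusted p = 0.50 with an estimated correlation), with the ubiquitin-like gene Isg15 at 1.60 ± 0.29. Of 16 antigen presentation genes 5 rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.50 with an estimated correlation), with the class I gene H2-K1 at 1.12. The medians of these lists stood at 0.26 at 16 and 0.65 at 28 weeks for interferon response, at 0.044 and 0.47 for antigen presentation, and at 0.051 and 0.40 for the macrophage markers on the same arrays (camera adjusted p = 0.557 with an estimated correlation).

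Secretory genes fell in TRAMP DLP. Wfdc3 fell by 5.15 ± 0.19 (limma adjusted p = 2.31e-05), and so did the gasdermin gene Gsdma at -3.29 ± 0.48, Pbsn at -3.09 ± 0.40 (limma adjusted p = 0.00348) and Tgm4 at -1.82 ± 0.30. Of 19 secretory genes 9 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.363 with an estimated correlation). Of 20 unfolded protein response genes 10 fell (14 adjusted over the list alone; camera adjusted p = 0.50 with an estimated correlation), with Asns, which makes asparagine, at -1.72 and Dnajc3 at -1.29. Of 15 adipocyte markers 7 rose (8 adjusted over the list alone; camera adjusted p = 0.363 with an estimated correlation), with the brown fat genes Cidea at 2.69 ± 0.30 and Ucp1 at 2.57 ± 0.36. Markers of neighbouring tissue differed between the same arrays: the median of the skeletal muscle list was 2.16 higher on the log2 scale in vehicle than in wild type at 16 weeks and stood at -1.84 at 28 weeks, and that of seminal vesicle genes at 2.93 and -1.19.

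**Figure D3:**
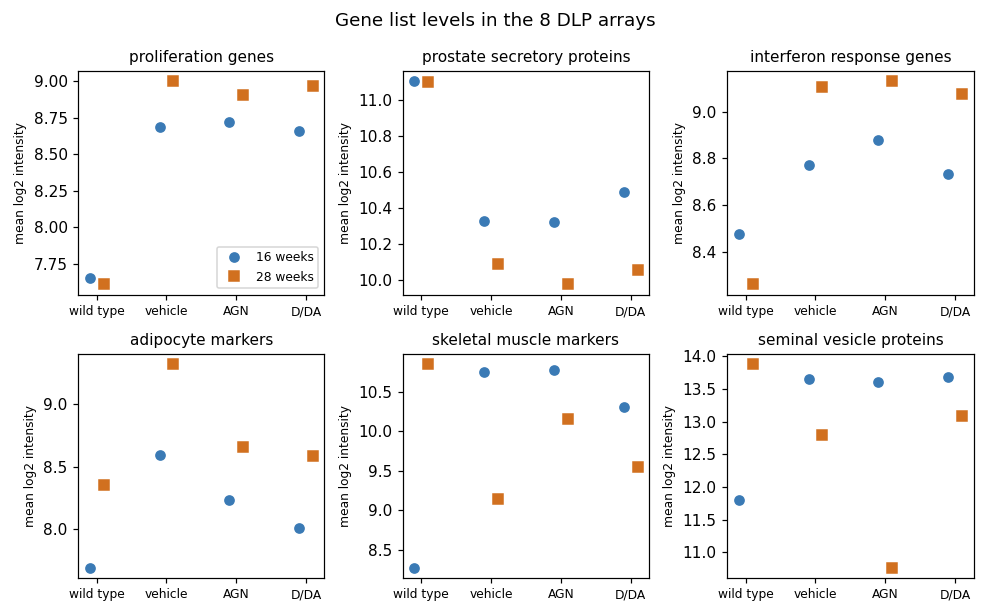
Mean log2 intensity of the genes of 6 lists (vertical axes, which do not start at 0) in the 8 DLP arrays, by treatment (horizontal axis), with 1 array per point and no replicates; circles are 16 weeks and squares 28 weeks. The adipocyte level was highest in vehicle at both ages (8.59 and 9.32), and the skeletal muscle level of wild type differed between 16 weeks (8.28) and 28 weeks (10.85).

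Limma called 1927 probes between vehicle and wild-type DLP, 775 higher and 1152 lower, for 1574 genes, and 7130 probes had an unadjusted p under 0.05. The split depended on scaling, with 786 higher and 713 lower after quantile normalization, 917 and 641 after median centring, and 852 and 736 after normexp correction. Camera called 10 lists at the preset correlation and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, and fry called 9. The numbers depended on single arrays. Limma called 504 probes without vehicle at 16 weeks, 333 without vehicle at 28 weeks, 878 without AGN at 16 weeks, 871 without AGN at 28 weeks and 2967 without wild type at 16 weeks. In the same order of arrays, the interferon genes that rose numbered 6, 2, 6, 6 and 23. Without vehicle at 16 and at 28 weeks, 1 and 0 antigen presentation genes, 4 and 1 adipocyte markers and 3 and 2 polycomb factors rose, and 5 and 3 secretory and 4 and 1 unfolded protein response genes fell, and without wild type at 16 weeks 8 antigen presentation genes rose. Tgm4 and Ezh2 missed the threshold without vehicle at 16 weeks (limma adjusted p = 0.0878 and 0.144) and at 28 weeks (0.0902 and 0.0876). Without vehicle at 28 weeks so did Tff3 (0.0727), Ucp1 (0.0644), Gsdma (0.0767), Pbsn (0.0563), Isg15 (0.108), H2-K1 (0.0944) and Asns (0.058). At a minimum of 2-fold, 377 probes differed at 16 weeks and 614 at 28 weeks, and 204 did so with the same sign at both ages and 62 with opposite sign. With the adipocyte level as a covariate limma called 0 probes (713 at an unadjusted p under 0.05), but treatment and age together give 98.5% of the variance of that level. With the skeletal muscle level it called 4116, with array weights 1046 and in a fit of all 16 arrays 1014.

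AGN and D/DA were each compared with vehicle in DLP to ask whether the extract and its pyranocoumarins change the DLP of TRAMP mice. Limma called 0 probes for AGN, with 1168 (4.55%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.927, and 0 probes for D/DA, with 2157 (8.39%) and a smallest adjusted p of 0.169. The named genes below therefore did not pass in these fits. Lower values with both treatments were seen for Thrsp, a regulator of lipogenesis, at -1.30 ± 0.18 with AGN and -1.62 ± 0.18 with D/DA, for the thermogenic genes Ucp1 at -1.46 ± 0.36 and -1.54 ± 0.36 and Cidea at -1.44 ± 0.30 and -1.68 ± 0.30, and for the adiponectin gene Adipoq at -0.92 ± 0.32 and -1.33 ± 0.32. The hemoglobin gene Hba-a1 stood at -0.81 with AGN and -1.08 ± 0.12 with D/DA, and the matrix gene Sparc at -0.64 and -0.62 ± 0.15. The secretoglobin gene Scgb2b27 was at 1.65 ± 0.26 with AGN and 0.47 ± 0.26 with D/DA. Adjusted over the list alone, 15 of 28 fibroblast and matrix genes fell with AGN and 12 with D/DA (camera adjusted p = 0.142 and 0.118 with an estimated correlation; fry adjusted p = 0.0278 and 0.0329), where over all probes 0 did. Of 15 adipocyte markers 4 fell with AGN and 9 with D/DA adjusted over the list alone (camera adjusted p = 0.155 and 0.118 with an estimated correlation; fry adjusted p = 0.269 and 0.168). Of 21 sterol and fatty acid synthesis genes 2 and 1 fell adjusted over the list alone (camera adjusted p = 0.155 and 0.118 with an estimated correlation; fry adjusted p = 0.0457 and 0.0772). The adipocyte level that these genes moved with was higher in vehicle (8.59 at 16 and 9.32 at 28 weeks) than in wild type (7.69 and 8.35), AGN (8.23 and 8.66) and D/DA (8.01 and 8.58). With normexp correction the means of other stromal lists were negative too, at -0.20 and -0.34 with AGN and D/DA for endothelial, -0.18 and -0.24 for smooth muscle, -0.20 and -0.22 for macrophage and -0.48 and -0.42 for fibroblast and matrix genes. Markers of other tissues differed between the same arrays: with AGN at 28 weeks the median of the skeletal muscle list stood 1.15 above vehicle (17 of 18 genes higher) and that of seminal vesicle genes at -2.38 (8 of 9 lower). With D/DA the skeletal muscle list stood at -0.43 at 16 weeks (17 of 18 lower) and 0.34 at 28 weeks (16 higher).

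Camera at the preset correlation called 10 lists for AGN and 16 for D/DA, all lower, and 0 with an estimated correlation for either, where 3 and 3 had an unadjusted p under 0.05, and fry called 3 and 2. The spread in these fits included the difference between the wild-type arrays of both ages. When wild type at 16 weeks was left out, limma called 11 probes for AGN and 12 for D/DA, without wild type at 28 weeks 8 and 12, and without vehicle at 16 weeks 48 and 50. In the fit without wild type at 16 weeks, Thrsp, Ucp1 and Cidea passed for AGN (limma adjusted p = 0.00248, 0.00148 and 0.0259) and for D/DA (0.00154, 0.00174 and 0.00942), Scgb2b27 passed for AGN (0.00138), and Hba-a1 and Adipoq for D/DA (0.0102 and 0.0222). Without wild type at 28 weeks the estimates were identical. Whichever wild-type array is left is fitted exactly, and the same TRAMP arrays set the estimates and their spread. The fit without wild type at 28 weeks is therefore no second check. Without vehicle at 16 weeks, Thrsp passed for D/DA (limma adjusted p = 0.0426). The skeletal muscle level as a covariate gave 11 probes for AGN and 5 for D/DA, and array weights gave 1 for D/DA. At a minimum of 2-fold, 11 probes differed with AGN at 16 weeks and 111 at 28 weeks, 6 of them with the same sign at both ages, and 9 and 89 differed with D/DA, 7 with the same sign, all lower.

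Whether the extract and the isolated pyranocoumarins differ was tested directly, at doses that are not given here. Limma called 0 of 25697 probes between AGN and D/DA, with 768 (2.99%) at an unadjusted p under 0.05, and camera called 4 lists at the preset correlation, all higher with AGN, and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05, while fry called 0, with 1 unadjusted. Scgb2b27 was 1.19 higher with AGN on the log2 scale (95% interval 0.60 to 1.77, limma adjusted p = 1.00). The apolipoprotein gene Apod was 0.97 higher (0.41 to 1.52) and the cytochrome gene Cyp2e1 0.69 higher (0.27 to 1.11), and neither passed. The difference was 0.31 for Thrsp (-0.10 to 0.72), 0.08 for Ucp1 (-0.73 to 0.89), 0.24 for Cidea (-0.44 to 0.92), 0.41 for Adipoq (-0.33 to 1.15) and -0.02 for Sparc (-0.36 to 0.31). Among the 12848 probes above the median level the 95% interval lay within 2-fold for 12673 (98.6%), with a median half-width of 0.25. Dimmer probes have narrow intervals because the background compresses them. These intervals are not adjusted for the number of probes, and a test that misses the threshold does not show that the preparations act alike. Limma called 4 probes without wild type at 16 weeks and 4 without wild type at 28 weeks, Scgb2b27 among them (limma adjusted p = 0.0115 and 0.0135), and 7 with the skeletal muscle level as a covariate.

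Whether AGN or D/DA turned back the difference between TRAMP and wild type was examined across probes. The correlation of the vehicle minus wild-type difference with the AGN minus vehicle difference of the other age was 0.07, at 0.087 and 0.053 in the pairings of the ages, and that with D/DA was 0.04, at 0.096 in one pairing and -0.024 in the other. Simulated unchanged groups gave -0.01 for both. The signs were opposite in 53% of probes for AGN and 58.6% for D/DA, against 50% and 50.1% simulated. On these arrays the median over all probes stood at -0.065 for vehicle minus wild type, 0.016 for AGN and 0.039 for D/DA minus vehicle. Within an age, where the compared differences hold the same vehicle array, the correlations were -0.28 for AGN and -0.32 for D/DA, against -0.51 and -0.50 in simulated unchanged groups. The covariances there were -0.0168 and -0.0169, against simulated values of -0.0222 and -0.0218. The effects of AGN and D/DA correlated with each other at 0.12 across ages, at 0.25 in one pairing of the ages and -0.017 in the other, and at 0.67 within an age, against 0.51 simulated, with a covariance of 0.0215 against 0.0224. The simulated groups held no difference between TRAMP and wild type either. Such a difference alone weakens the correlation within an age for reversal. The simulated correlations there are therefore not what an absence of reversal would give. The simulated spread came from the residuals of the additive fit, which also hold the difference between the wild-type arrays. It can be wider than array noise, so the values within an age cannot tell reversal or likeness from the shared array.

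The comparison of 28 with 16 weeks in DLP asked what changes with age over all 4 treatments, wild type among them. Mmp7, which encodes the protease matrilysin, rose by 1.15 ± 0.08 (limma adjusted p = 0.00673), the aspartic protease gene Ctse by 1.67 ± 0.19 (limma adjusted p = 0.0338), the haptoglobin gene Hp by 1.25 ± 0.12 and the interferon-induced gene Ifi27l2a by 1.23. Also called higher were Thrsp at 1.28 ± 0.13, Cidec, a lipid droplet protein gene, at 0.98, the adipocyte transcription factor gene Pparg at 0.83 and Dgat2, which makes triglycerides, at 0.74. The cyclin D1 gene Ccnd1 fell by 1.09 ± 0.14 and the growth factor binding gene Fgfbp1 by 0.86. Adjusted over the list alone, 7 of 15 adipocyte markers rose (camera adjusted p = 0.415 with an estimated correlation), 11 of 20 macrophage markers rose and 1 fell (camera adjusted p = 0.482 with an estimated correlation), and 0 of 40 proliferation genes passed (camera adjusted p = 0.488 with an estimated correlation). Limma called 20 probes, 12 higher and 8 lower, and 2266 had an unadjusted p under 0.05. Camera called 19 lists at the preset correlation and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and fry called 2. Every one of these calls depended on single arrays: limma called 418 and 412 probes without wild type at 16 or 28 weeks, 1 (Mmp7) without D/DA at 28 weeks, and 0 without any 1 of the other 5 arrays, with 1424 to 1967 at an unadjusted p under 0.05. It also called 1 among probes above the median level, 1 without an intensity trend, 143 with array weights, 376 with the skeletal muscle level as a covariate and 0 with the adipocyte level (399 at an unadjusted p under 0.05).

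Whether the AGN effect differs between NECa and DLP was tested by an interaction. Dbx1 differed by 3.65 ± 0.42 (limma adjusted p = 0.017), with an AGN effect of 3.73 in NECa and 0.07 in DLP, and Fam171b by -1.67 ± 0.21 (limma adjusted p = 0.017), with -1.88 and -0.22. Sct differed by 1.5 ± 0.20 (limma adjusted p = 0.0281), with 1.27 and -0.23, and 6330403K07Rik by -2.96 ± 0.39 (limma adjusted p = 0.0281), with -3.13 and -0.17. Limma called these 4 probes, and 1331 had an unadjusted p under 0.05. A small effect in DLP can also come from a level near background, where differences are compressed. Dbx1 lay below the median probe in wild-type whole prostate, and the DLP levels of the 4 genes are not given here. The interaction therefore does not show that the tissues respond differently to AGN. Camera called 6 lists at the preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and fry called 0, with 2 unadjusted. Limma called 0 probes without vehicle DLP at 28 weeks (686 unadjusted), 0 without AGN DLP at 28 weeks (686 unadjusted) and 1 without AGN DLP at 16 weeks, which was none of the 4, and 2 (Dbx1 and Fam171b) without D/DA DLP at 16 or at 28 weeks. It called 28 without NECa vehicle 1, 23 without NECa vehicle 3, 25 without NECa AGN 1 and 44 without vehicle DLP at 16 weeks. Sct missed the threshold without NECa vehicle 2 (limma adjusted p = 0.0587), NECa AGN 2 (0.0625), wild-type DLP at 16 weeks (0.0548) or at 28 weeks (0.0549), and 6330403K07Rik without NECa AGN 2 (0.0625). After normexp correction limma called 0 (1716 unadjusted), without an intensity trend 11 and with gene-by-gene array weights 186.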

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

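The interaction that picked out the first 4 genes here was set before the data were examined, while the tests of other splits of the carcinomas, of muscle tissue and of the transgene were chosen after the results were seen. The AGN effect differed between carcinomas and DLP, by an interaction term, for Dbx1 (3.65), Sct (1.5), Fam171b (-1.67) and 6330403K07Rik (-2.96), as log2 values. A level near background in DLP would also give such a difference, and the DLP levels of these genes are not given here. None of the 4 passed after normexp correction, where the differences were larger (4.79, 2.06, -2.90 and -4.20). Their limma adjusted p was 0.017 for Dbx1 and Fam171b and 0.0281 for the others, and over the other settings, single arrays left out aside, it ranged from 8.66e-05 with gene-by-gene weights to 0.210 after normexp correction. Sct also missed the threshold after median centring (0.0804) and 6330403K07Rik without an intensity trend (0.0509).

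The carcinoma side of that interaction rests on 3 against 3 arrays. The 6 carcinomas can be split in 10 ways, of which 1, the real one, gave as many as 10 called probes, and the highest of the others gave 2. With 10 splits no share under 5% can be reached, and nothing more is claimed from them. At an unadjusted p under 0.05 the real split gave 1578 probes, and the split of vehicle 1, vehicle 3 and AGN 2 against the rest gave 5455 with 0 probes called by limma. Those 3 arrays also had lower median intensities (155, 162 and 161) than the rest (166 each), and what sets them apart was not tested.

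Skeletal muscle and seminal vesicle genes changed sides between the ages in the difference of vehicle from wild-type DLP. The list median of the skeletal muscle markers was 2.16 at 16 weeks and -1.84 at 28 weeks, and that of the seminal vesicle proteins was 2.93 and -1.19. The change of sides was not tested, since each group and age had 1 array. Of the 18 muscle genes 15 were at least 2-fold higher at 16 weeks and 15 at least 2-fold lower at 28 weeks, and an effect of the TRAMP transgene stays open, because the -1.84 is the change of sides itself and 1 array per group and age gives no spread to set it against. A candidate source is skeletal muscle tissue left in some samples, since 15 of the 18 genes were also at least 2-fold higher in wild-type whole prostate 1 than in 2, arrays of 1 group (median 2.48).

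Of the skeletal muscle genes 0 belong to another list, and 11 lay above the median probe in the array with the lowest level of the list, wild-type DLP at 16 weeks. Myl1, a myosin light chain gene of fast fibres, had an intensity of 16960 in whole prostate 1 and 1691 in 2, and in DLP of 718 in wild type and 13850 in vehicle at 16 weeks and of 16420 and 3717 at 28 weeks. The troponin gene Tnnc2 had 13009 and 2407 in the whole prostates, 2251 and 8793 at 16 weeks and 10645 and 2892 at 28 weeks. How the tissue was trimmed is not given in the sources used here.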

How the results depend on the processing

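The settings added after the data were examined were normexp correction, gene-by-gene array weights, list levels as covariates, leaving out chromosome 19 genes and leaving out NECa vehicle 1 and AGN 2 together. Over the settings chosen beforehand, leaving out single arrays aside, the values of named genes and of lists kept their direction and their side of the threshold in 982 cases, lost the threshold in 63, gained it in 4, moved as counts in 6 and changed sign in 0. Over the added ones these numbers were 544, 72, 10, 12 and 17. Over both sets, 40 losses fell in AGN against vehicle NECa, 41 in age, 47 in vehicle against wild-type DLP and 6 in the interaction. Against wild-type prostate there were 1 for vehicle and 0 for AGN NECa. A gene that was not called in either setting counts as kept. For AGN and D/DA in DLP, where 0 probes were called, the kept cases therefore show no stable calls. Where nothing else is said, the cause of a change was not tested.

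Between AGN and vehicle NECa limma called 10 probes, 6 after quantile normalization, 6 after median centring, 0 among probes above the median level (1335 at an unadjusted p under 0.05), 35 without an intensity trend, 405 with gene-by-gene weights, 0 after normexp correction (2049 unadjusted), 0 without vehicle 1 and AGN 2 (1602 unadjusted), and 7 to 72 when 1 array was left out. Normexp correction gave 11844 probes for vehicle and 12712 for AGN NECa against wild type and 0 for the interaction (1716 unadjusted), and a minimum of 2-fold gave 3052 and 3231. By construction that minimum can only lower a count. The leave-one-out ranges were 5840 to 8184 and 6371 to 9090, with NECa vehicle 1 the array whose absence gave the highest. The interaction had 4 probes, 11 without a trend, 186 with gene-by-gene weights and 0 to 44 in leave-one-out fits.

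In DLP, vehicle against wild type had 1927 probes, 1046 with array weights, 1068 with gene-by-gene weights, 1014 in the fit of all 16 arrays and 333 to 2967 in leave-one-out fits. AGN against vehicle had 0 (0 to 48 in leave-one-out fits), D/DA against vehicle 0 (1 with array weights, 1 with gene-by-gene weights, 0 to 50) and AGN against D/DA 0 (0 to 4). The 28 against 16 weeks difference had 20, 1 among probes above the median level, 1 without a trend, 143 with array weights, 131 with gene-by-gene weights and 0 to 418. A fit that leaves out 1 array assumes for a lone array the spread of the others. Leaving out either array of a treatment that a comparison does not hold, or for age of any treatment, gives the same estimates. Such a pair of fits is not a repeated check. In leave-one-out fits Chga in vehicle against wild type ranged from -0.017 (without vehicle at 28 weeks) to 0.071, and the difference of AGN from D/DA from -0.027 (without AGN at 16 weeks) to 0.84 for Adipoq, from -0.28 (without D/DA at 16 weeks) to 0.76 for Cidea, from -0.39 (without D/DA at 16 weeks) to 0.56 for Ucp1, which was also negative without AGN at 28 weeks (-0.051), and from -0.19 to 0.14 (without AGN at 28 weeks) for Sparc, which was also positive without D/DA at 16 weeks (0.023).

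The skeletal muscle level as a covariate gave 4116 probes for vehicle against wild type, 11 for AGN, 5 for D/DA, 7 for AGN against D/DA and 376 for age. The adipocyte level gave 0 for vehicle against wild type (713 unadjusted) and 0 for age (399 unadjusted) and turned the sign of Cbr2 (1.47), Chga (-0.28), Car3 (-1.90) and Flt1 (0.48) in vehicle against wild type, of Sparc (0.059), Lum (1.00) and Adipoq (1.15) with AGN, of Cidec (0.67), Cyp2e1 (0.59), Sparc (0.28), Adipoq (1.35) and Scgb2b27 (-1.04) with D/DA, of Adipoq (-0.19) between these, and of Hp (-0.20), Cyp2e1 (-0.31), Cidec (-0.60) and Dgat2 (-0.067) with age. Treatment and age give 98.5% of the variance of the adipocyte level and 14.2% of that of the muscle level, so the adipocyte covariate leaves little to estimate.

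With an estimated correlation, camera called 0 lists in each of the 9 comparisons, where the preset one called 8, 20, 19, 10, 10, 16, 4, 19 and 6, and after quantile normalization the preset one called 3 between AGN and vehicle NECa, 2 between AGN and D/DA and 3 in the interaction. Folds at a single age rose in number with a log2 minimum of 0.6 in place of 1, by construction, and with normexp correction: 1164 and 1034 for vehicle against wild type at 16 weeks and 1663 and 1459 at 28 weeks, 35 and 89, then 295 and 292 for AGN against vehicle, 79 and 89, then 328 and 297 for D/DA against vehicle, and 72 and 98, then 73 and 83 for AGN against D/DA. Correlations within an age, which share the vehicle array, were -0.28 and -0.32 for the reversal by AGN and D/DA and 0.67 for their likeness.

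The replicate numbers do not pair the carcinomas: vehicle and AGN NECa of the same number correlated at -0.04, -0.26 and 0.16 after group means were removed, and the highest of all pairs was 0.32, vehicle 1 with AGN 2. With the number as a block limma called 502 probes between AGN and vehicle NECa, and 6759 and 7084 against wild type, and of 83 named values 3 gained the threshold (Stmn2, Resp18 and Scg2) and 80 were the same.

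Not run were a chip block, since no chip is named in the columns used, a filter on detection, since no detection p was usable, and a fit without a filter, which is the fit reported. Array weights by REML were set aside in the 3 carcinoma fits and the interaction, where the estimation did not converge and NECa vehicle 3 took a weight of 97.9, 82.0, 82.0 and 103, and the counts as fitted (3335, 10155, 8803 and 687) are not compared with the others.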

Other observations

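The tests of chromosomes against alternative explanations were set before their values were seen, apart from 1 bound that was changed afterwards and is named below, and the tests of adipocyte genes were chosen after the result was seen. In vehicle NECa, part of the basal cell, drug-metabolism and antigen presentation lists fell against wild-type prostate, where 4197 of all 25697 probes fell. Of 16 basal epithelial markers 8 fell (9 adjusted over the list alone; camera adjusted p = 0.297 with an estimated correlation), among them the basal keratin gene Krt14 at -2.98 and the transcription factor gene Trp63, a marker of basal cell nuclei, at -2.01. Of 18 AhR and drug-metabolism genes 9 fell (9 adjusted over the list alone; camera adjusted p = 0.166 with an estimated correlation). Of 16 antigen presentation genes 5 fell (6 adjusted over the list alone; camera adjusted p = 0.609 with an estimated correlation), including B2m, the light chain gene of class I molecules, at -2.93, although 1 of its 3 probes had the opposite sign. In vehicle DLP 5 of these 16 genes rose against wild type, and whether the carcinomas and DLP differ in this was not tested. The androgen-responsive protease gene Tmprss2 fell in NECa, at -4.67, and in vehicle DLP, at -1.33, where it missed the threshold without vehicle at 16 weeks (limma adjusted p = 0.0799) or at 28 weeks (0.119).

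Between AGN and vehicle NECa 3 neuroendocrine genes with low values did not pass. The granin gene Scg2 stood at -1.33 ± 0.28 (limma adjusted p = 0.163), the granule gene Resp18 at -1.45 ± 0.31 (0.168) and the neuronal tubulin-binding gene Stmn2 at -1.77 ± 0.60 (0.563). Without vehicle 3, Scg2 passed at -1.72 (limma adjusted p = 0.000582), and without AGN 1, Resp18 passed at -1.87 (0.00165). Over the 38 neuroendocrine markers the median was -0.04 and 22 were lower, with Chga at 0.22 ± 0.18 (camera adjusted p = 0.733 with an estimated correlation).

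Chromosome 19 genes were lower in AGN than in vehicle NECa, with a median of -0.42 over 312 genes, a ratio of 0.746. The tables argue against a difference in normalization between arrays, since the medians of the other chromosomes lay between -0.03 and 0.09, and against a few genes, since 3 equal parts of the chromosome in map order had medians of -0.48, -0.39 and -0.41 (104 genes each). After normexp correction the ratio to other genes was 0.732 among the genes of the lowest level and 0.609, 0.584 and 0.601 in the 3 groups above. Against wild-type prostate the chromosome stood at -0.52 ± 0.036 in AGN and -0.12 ± 0.003 in vehicle NECa (SD, n = 3 each). Between AGN and vehicle NECa the list of its genes had a camera adjusted p of 8.53e-63, or 0.00119 with an estimated correlation, and a fry adjusted p of 0.000148. Chromosomes 3, 9 and 12 passed in the other direction at the preset correlation (camera adjusted p = 3.37e-05, 0.0106 and 0.00319), with medians of 0.095, 0.063 and 0.077, and had 0.796 each with an estimated correlation. On chromosome 9 only AGN 2 stood apart, with a deviation from the median of the NECa of 0.154, against -0.023 to -0.007 in the others. On chromosome 3 the deviation was 0.158 in AGN 1, -0.019 in AGN 2 and 0.013 in AGN 3, against -0.054 to -0.006 in vehicle NECa. A candidate explanation is a chromosome 19 loss shared by the AGN carcinomas, which no measurement of DNA tested here.

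Whether carcinomas differ in chromosome levels whatever the treatment cannot be told apart from an effect of treatment in these carcinomas. In DLP the median difference of AGN from vehicle over the 312 chromosome 19 genes was -0.00017. No shift of these genes with AGN was thus seen in DLP, where 1 array stands for each treatment and age. DLP does not show what AGN does in carcinomas. The bound set beforehand compared single tumours on other chromosomes, at most 0.158, with the difference of the group means on chromosome 19, -0.37. No other chromosome in any tumour deviated by as much, the outcome set beforehand as against this explanation. The comparison was changed after the values were seen, to the smallest deviation of a tumour on chromosome 19, 0.160, beside the 0.158. Those values are not alike, since a deviation from the median of 6 shows a change of 1 tumour in full and a split of 3 against 3 only in part. Against wild-type prostate chromosome 19 stood at -0.48 to -0.54 in AGN and -0.12 in each vehicle NECa. On chromosome 3, which held the 0.158, AGN 1 stood at 0.130 and the other NECa at -0.069 to 0.040. The sizes do not settle the cause, since 3 tumours stand for each treatment. The exact permutation p of 0.1 was the smallest possible, and whether the tumours arose independently is not given in the sources used here.

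Adipocyte markers were lower with AGN and with D/DA than with vehicle in DLP, at both ages for 12 and 11 of 15 genes. The other stromal lists were lower as well, but fewer stromal cells of every kind would lower them alike, and the tables argue against that as the whole cause: with normexp correction the adipocyte minus the endothelial list mean was -0.56 with AGN (95% interval -0.79 to -0.33, from the spread between arrays with 3 residual degrees of freedom) and -0.66 with D/DA (-0.89 to -0.43), and the adipocyte minus the smooth muscle list mean was -0.57 (-1.04 to -0.10) and -0.76 (-1.23 to -0.29). The intervals against fibroblast and macrophage genes reached 0. Vehicle was the highest of the 4 treatments in 10 of 15 genes at 16 weeks and in 14 at 28 weeks, which vehicle arrays with more fat and an effect of the preparations would both give. Of these genes 0 belong to another list, and 6 lay above the median probe in wild-type DLP at 16 weeks, the array with the lowest level. These explanations cannot be told apart, since 1 array stands for each treatment and age.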
